A study of Canis lupus with 24 samples.

How the data were processed

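Expression was measured in the canine bladder transitional cell carcinoma line K9TCC on 24 Affymetrix Canine Gene 1.1 ST arrays, 3 in each of 8 groups set by culture form and treatment. The deposited values are log2 signals, 1 per array feature and array, and ran from 0.60 to 13.51. Affymetrix Expression Console 1.1 was used per the submitters' processing notes, and the summarisation and normalization methods are not given in the sources used here. The values carry no detection calls, so a difference whose lower group lay under 4.82, the median of all values, is a lower bound where that signal is background, and the number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical only.

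The table held 27766 features, of which 16878 carried 1 gene symbol, 289 several and 10599 none. For 521 genes with several features (1104 features) the feature with the highest mean over all arrays was taken, which left 16295 genes with no filter on intensity. Symbols are those of the platform annotation and were not updated; 14154 of them also occur in the gene table of the Canis lupus baileyi assembly mCanLup2.hap1, which was used only for names and for the order of genes.

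A model with 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes; 16 residual and 5.54 prior degrees of freedom). The 10 comparisons were mavacoxib with DMSO and COX-2 siRNA with negative siRNA in each culture form, spheres with adherent cells in each control, and 4 differences between such effects. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over all genes of a comparison. In total 36 gene lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry; of 836 list genes 738 were measured. The lists included the prostaglandin pathway, stem cell markers, and markers of fibroblasts, leukocytes, and endothelium and muscle.

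Genes are named by a rule: PTGS2 throughout, in each comparison of groups the 10 largest rises and 10 largest falls that passed with separated arrays, up to 4 members of each list with the smallest adjusted p, and for differences between effects the 5 largest in each direction. Within this rule, examples were preferably those whose call held under every alternative. Members of small list counts outside the rule were named after their values were seen. The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were quantile normalization, shifting arrays to one median, leaving out dim genes, all features or the mean of the features of a gene in place of the brightest one, only the arrays of a comparison, trend and robust variance, array weights, blocks of equal replicate numbers, and leaving out each array.

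The procedure was tested on simulated data with the group sizes and spread of the arrays. Each size of change was given to 66 or 67 of 16295 genes, and the noise was independent between genes. More genes passed in the real comparisons, so recovery and false calls may differ there. For mavacoxib in adherent cells it recovered 23.9% of genes changed by 0.5, 89.6% of those changed by 1 and 100% of those changed by 2 on the log2 scale, with 6 false calls among 148. For the 4 differences between effects it recovered 2.99% to 11.9% at 0.5 and 62.7% to 67.2% at 1, and for siRNA in adherent cells 12 of 159 calls were false. Replicate numbers gave no clear pairing of the arrays, since only 6 of 18 pairs of equal number correlated above 0.1 after group means were removed. These correlations ran from -0.171 to 0.266. With 3 arrays per group the check is weak and cannot exclude a pairing in some groups. No pairing was used in the main fit. Features without exactly 1 gene symbol were left out of the gene tests.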

Results

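Gene expression was measured in K9TCC, a cell line from a canine bladder transitional cell carcinoma, on 24 Affymetrix Canine Gene 1.1 ST arrays in 8 groups of 3. The cells were grown either attached to plastic in medium with serum (adherent cells) or as cancer stem cell spheres in serum-free medium with growth factors. Each culture form received 50 µM mavacoxib, an inhibitor of the prostaglandin-producing enzyme COX-2, or its vehicle DMSO for 24 h, or was transfected with a COX-2 siRNA or a negative control siRNA for 48 h. Values are log2 signals, array medians lay between 4.68 and 5.02, and 3 arrays per group limit the precision. Arrays of a group correlated at 0.981 to 0.996, and sphere with adherent arrays at 0.916 to 0.941. Changes are log2 differences ± standard error of the limma fit over all 24 arrays, tested for 16295 named genes. A gene rose or fell where its Benjamini-Hochberg adjusted p was under 0.05. The comparisons address how each culture form responded to mavacoxib and to the labelled COX-2 siRNA, whether the responses differed between culture forms and between mavacoxib and the labelled siRNA, and how the culture forms differed.

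PTGS2, the gene of COX-2, was not lower in the arrays labelled COX-2 siRNA. In adherent cells it read 11.27, 11.50 and 11.20 in the arrays labelled COX-2 siRNA and 11.06, 10.89 and 11.02 in those labelled negative siRNA, a difference of 0.33 ± 0.13 that did not pass (adjusted p = 0.0888). In spheres it read 11.32, 11.51 and 11.59 against 10.30, 10.29 and 10.35, and was 1.16 ± 0.13 higher in the arrays labelled COX-2 siRNA (adjusted p = 2.57e-07). Because PTGS2 went against the label, these arrays are named by their label throughout, and a direction drawn from them is a direction between labelled arrays. With DMSO, PTGS2 read 9.59, 9.70 and 9.50 in adherent cells and 12.13, 12.13 and 12.07 in spheres. With mavacoxib it read 9.15, 9.59 and 9.70 in adherent cells and 12.25, 11.93 and 11.99 in spheres. The change with mavacoxib was -0.12 ± 0.13 in adherent cells (adjusted p = 0.747) and -0.05 ± 0.13 in spheres (adjusted p = 0.846), and neither passed. Without mavacoxib array 1 the adherent difference was 0.05, and without mavacoxib array 2 the sphere difference was 0.01.

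**Figure D1:**
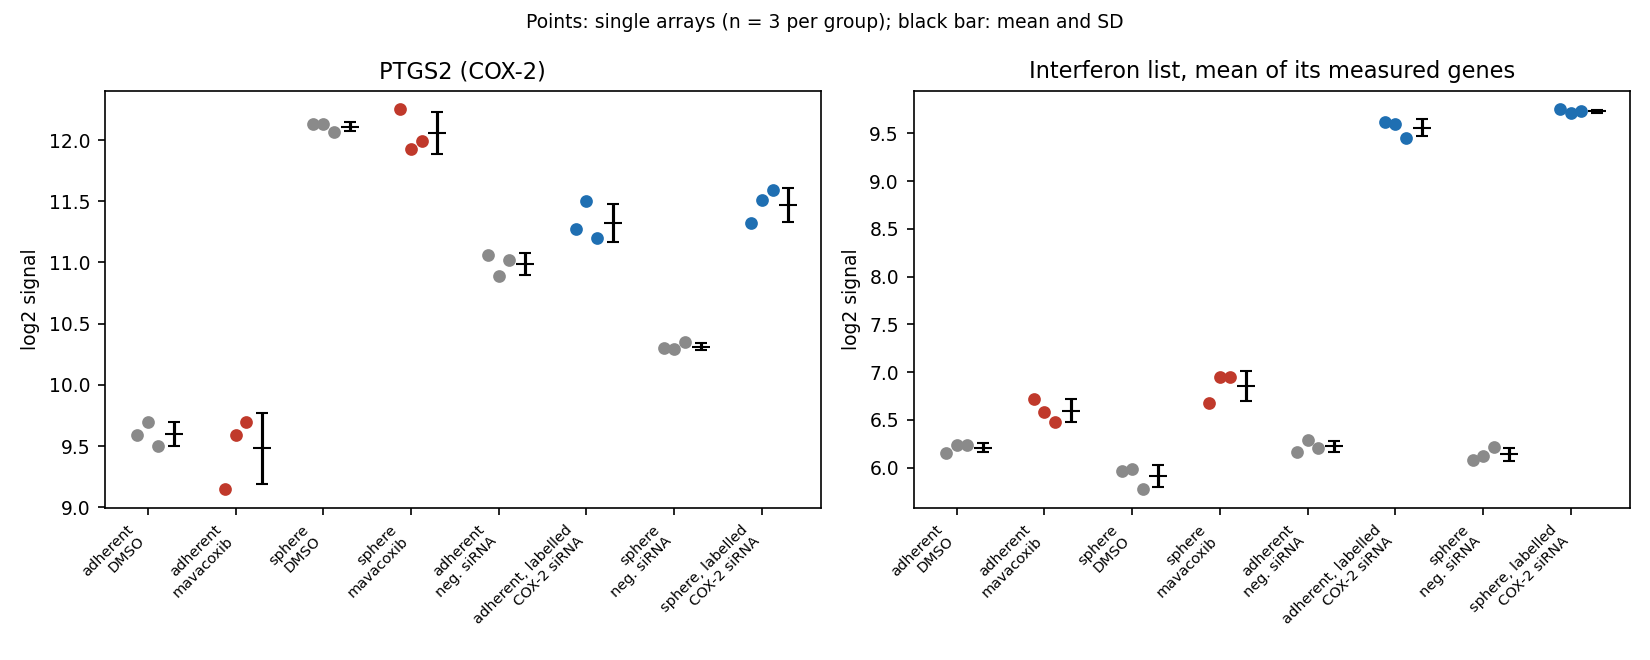
Log2 signal of PTGS2 (left) and mean log2 signal of the 32 measured interferon response genes (right) in the 8 groups; points are single arrays and black bars the mean and SD (n = 3). PTGS2 lay between 11.32 and 11.59 in the sphere arrays labelled COX-2 siRNA and between 10.29 and 10.35 in those labelled negative siRNA, and the interferon mean was at least 9.46 in the arrays labelled COX-2 siRNA and at most 6.95 in all others.

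In adherent cells, targets of ATF4, the transcription factor of the integrated stress response, rose after 24 h of mavacoxib, and genes of DNA replication and mitosis fell. DDIT3, which encodes the stress-induced transcription factor CHOP, rose by 1.81 ± 0.15, the stress-induced pseudokinase TRIB3 by 1.30 ± 0.12 and the stress-induced sestrin SESN2 by 1.14 ± 0.11. RRM2, a subunit of ribonucleotide reductase, fell by 1.17 ± 0.12, while the changes were -0.84 ± 0.11 for E2F1, a transcription factor of S-phase entry, and -0.77 ± 0.12 for the mitotic checkpoint kinase TTK. The largest rise was that of CHN1, a Rac GTPase-activating protein, at 2.96 ± 0.28, followed by RSAD2, an interferon-induced antiviral protein, at 2.03 ± 0.14. SLC15A2, a peptide transporter, had the largest fall, -1.72 ± 0.19.

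Among 27 measured ATF4 targets, 15 rose, 0 fell and 12 did not pass (22 and 0 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 1.6e-23). The list of G1/S and DNA replication held 33 genes, of which 0 rose, 15 fell and 18 did not pass (0 and 23 adjusted over the list alone, median -0.43, camera adjusted p = 9.54e-25). Mitosis genes followed, with 0 of 34 higher, 14 lower and 20 not passing (0 and 23 adjusted over the list alone, median -0.42, camera adjusted p = 1.6e-23). The lower count was 8 with every array shifted to the same median and 21 after quantile normalization. Cholesterol synthesis genes fell as a list, 4 of 17 passing with 0 higher (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 3.51e-08), among them HMGCS1, an early enzyme of the pathway, at -0.82 ± 0.12, and INSIG1, its sterol-sensing regulator, at -0.85 ± 0.13. These 4 lists also held with an estimated correlation. Interferon response genes had 8 higher, 1 lower and 23 not passing of 32 (16 and 2 adjusted over the list alone, camera adjusted p = 7.33e-06), a call that was lost at adjusted p = 0.174 with an estimated correlation; the 1 lower gene was CXCL10 at -0.83, named after its values were seen. Fatty acid synthesis genes had 0 higher and 5 lower of 17 (1 and 8 adjusted over the list alone, camera adjusted p = 2.22e-05, adjusted p = 0.174 with an estimated correlation), including FASN, the fatty acid synthase, at -0.67 ± 0.10. Endoplasmic reticulum chaperone and unfolded protein response genes had 2 higher and 0 lower of 22 (4 and 0 adjusted over the list alone, median 0.23). Their camera adjusted p was 0.0024, and 0.31 with an estimated correlation. No member of the 20 prostaglandin pathway genes passed, also when adjusted over the list alone (camera adjusted p = 0.546).

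Mavacoxib changed 671 genes in adherent cells, 426 higher and 245 lower, of which 68 changed at least 2-fold; 2645 genes had an unadjusted p under 0.05. The share of higher genes was 63.5% on the deposited values and 53.3% after quantile normalization. Array weights gave 2472 genes, while leaving out an array gave 344 without DMSO array 1, 427 without DMSO array 2, and 394, 421 and 414 without mavacoxib arrays 1, 2 and 3.

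In spheres, mavacoxib raised interferon-induced genes, endoplasmic reticulum stress genes and cholesterol synthesis genes. IRF1, an interferon-induced transcription factor, rose by 4.25 ± 0.18, the type III interferon gene IFNL1 by 3.91 ± 0.22, the ubiquitin-like antiviral protein ISG15 by 3.58 ± 0.21 and the chemokine CXCL10 by 3.33 ± 0.19. With DMSO IRF1 averaged 4.74, ISG15 3.28 and CXCL10 4.25, so the limit on signals under 4.82 applies to them. The stress genes PPP1R15A, which restores translation after stress, and ATF3, a stress-induced transcription factor, rose by 3.38 ± 0.20 and 2.76 ± 0.16. XBP1, a transcription factor of the unfolded protein response, rose by 1.77 ± 0.11 and HERPUD1, a component of endoplasmic reticulum protein degradation, by 1.99 ± 0.13. The largest falls were those of PRR9, a proline-rich epidermal protein, at -2.63 ± 0.21 and the lipopolysaccharide receptor CD14 at -2.35 ± 0.15. PMAIP1 and BCL2L11, which promote apoptosis, rose by 2.51 ± 0.16 and 1.71 ± 0.17. The list of apoptosis regulators had 3 higher, 2 lower and 13 not passing of 18 (3 and 2 adjusted over the list alone, median -0.01, camera adjusted p = 0.645).

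Interferon response genes had 20 higher, 2 lower and 10 not passing of 32 (21 and 2 adjusted over the list alone, median 0.61, camera adjusted p = 1.6e-12). Endoplasmic reticulum chaperone and unfolded protein response genes had 15 higher and 0 lower of 22 (16 and 0 adjusted over the list alone, camera adjusted p = 2.93e-13). For cholesterol synthesis the numbers were 15 and 0 of 17 (the same adjusted over the list alone, median 0.64, camera adjusted p = 3.92e-13), with INSIG1 at 1.61 ± 0.13, MVD, an enzyme of the mevalonate pathway, at 1.43 ± 0.11 and SQLE, the squalene epoxidase, at 1.17 ± 0.12. NF-kB and inflammatory genes had 15 higher and 1 lower of 26 (the same adjusted over the list alone, camera adjusted p = 1.61e-10), such as the cytokine gene TNF at 2.76 ± 0.21 and the NF-kB subunit RELB at 2.17 ± 0.15. ATF4 targets had 12 higher and 1 lower of 27 (18 and 1 adjusted over the list alone, camera adjusted p = 3.25e-10). Extracellular matrix and integrin genes fell, with 1 higher and 11 lower of 31 (1 and 19 adjusted over the list alone, median -0.41, camera adjusted p = 2.71e-07), including the laminin LAMA5 at -1.35 ± 0.12 and the basement membrane proteoglycan HSPG2 at -1.11 ± 0.13. Aryl hydrocarbon receptor (AhR) and xenobiotic response genes had 5 higher and 0 lower of 12 (the same adjusted over the list alone, camera adjusted p = 0.000481), with CYP1A1 at 1.95 ± 0.17 and CYP1B1 at 1.41 ± 0.16. These 7 lists held with an estimated correlation.

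DNA replication genes rose in spheres, with 16 higher, 2 lower and 15 not passing of 33 (17 and 2 adjusted over the list alone, median 0.30, camera adjusted p = 0.000153, adjusted p = 0.169 with an estimated correlation). The replication licensing factor CDC6 rose by 1.05 ± 0.13 and the helicase subunit MCM6 by 0.57 ± 0.09, whereas E2F1 fell by 0.71 ± 0.11. YAP targets fell with 0 higher and 8 lower of 19 (1 and 12 adjusted over the list alone, camera adjusted p = 0.000153, adjusted p = 0.132 with an estimated correlation), among them the matricellular protein CCN1 at -1.40 ± 0.16. The prostaglandin pathway had 0 higher and 2 lower of 20 (the same adjusted over the list alone, camera adjusted p = 0.645): the prostaglandin D2 receptor gene PTGDR fell by 0.74 ± 0.18, and the prostaglandin E synthase PTGES stood at -0.64 ± 0.19 with overlapping arrays (adjusted p = 0.0196). Stem cell markers had 4 higher and 4 lower of 23 (the same adjusted over the list alone, camera adjusted p = 0.904). Leukocyte markers had 1 higher and 2 lower of 12 (the same adjusted over the list alone, camera adjusted p = 0.470), the lower ones being CD14 and lysozyme, LYZ, at -1.72.

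Mavacoxib changed 3491 genes in spheres, 1812 higher and 1679 lower, and 448 of them at least 2-fold. The share of higher genes was 51.9% as deposited, 61.5% with every array shifted to the same median and 48.3% after quantile normalization. With only the 6 arrays of the comparison 1904 genes passed, and with array weights 5535. The call of PTGES was lost with only these 6 arrays and without DMSO array 1, DMSO array 2, mavacoxib array 2 or mavacoxib array 3, its values over all alternatives running from -0.86 to -0.44 with adjusted p up to 0.135.

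The response to mavacoxib differed between the culture forms at 1680 genes, 732 with a higher and 948 with a lower change in spheres. Replication genes carried part of this difference: 22 of 33 had a higher change in spheres and 0 a lower one (26 and 0 adjusted over the list alone, median 0.77, camera adjusted p = 1.95e-21). Cholesterol synthesis genes, which fell in adherent cells and rose in spheres, differed at 14 of 17 genes, all higher in spheres (16 and 0 adjusted over the list alone, median 0.88, camera adjusted p = 8.83e-21). NF-kB and inflammatory genes differed with 13 higher and 1 lower of 26 (13 and 2 adjusted over the list alone, camera adjusted p = 4.29e-11). All 3 lists held with an estimated correlation. Mitosis genes had 20 higher and 0 lower of 34 (27 and 0 adjusted over the list alone, camera adjusted p = 3.72e-18), which was lost at adjusted p = 0.0516 with an estimated correlation. Single genes with the largest differences were IRF1 at 4.24 ± 0.25, CXCL10 at 4.16 ± 0.27 and IFNL1 at 4.02 ± 0.30, and at the other end CHN1 at -2.82 ± 0.39 and PRR9 at -2.74 ± 0.30. The changes of all genes correlated between adherent cells and spheres at a Pearson r of 0.172 and a Spearman rho of 0.175 across genes, which are not independent replicates. Of 297 genes that passed in both forms, 69.4% moved the same way; 146 were higher in both against 47.4 for independent lists, and 60 were lower in both against 25.2. In opposite directions, 58 genes were lower in adherent cells and higher in spheres against 27.2. The reverse held for 33 against 43.9. Array weights gave 3950 genes with a different response.

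**Figure D2:**
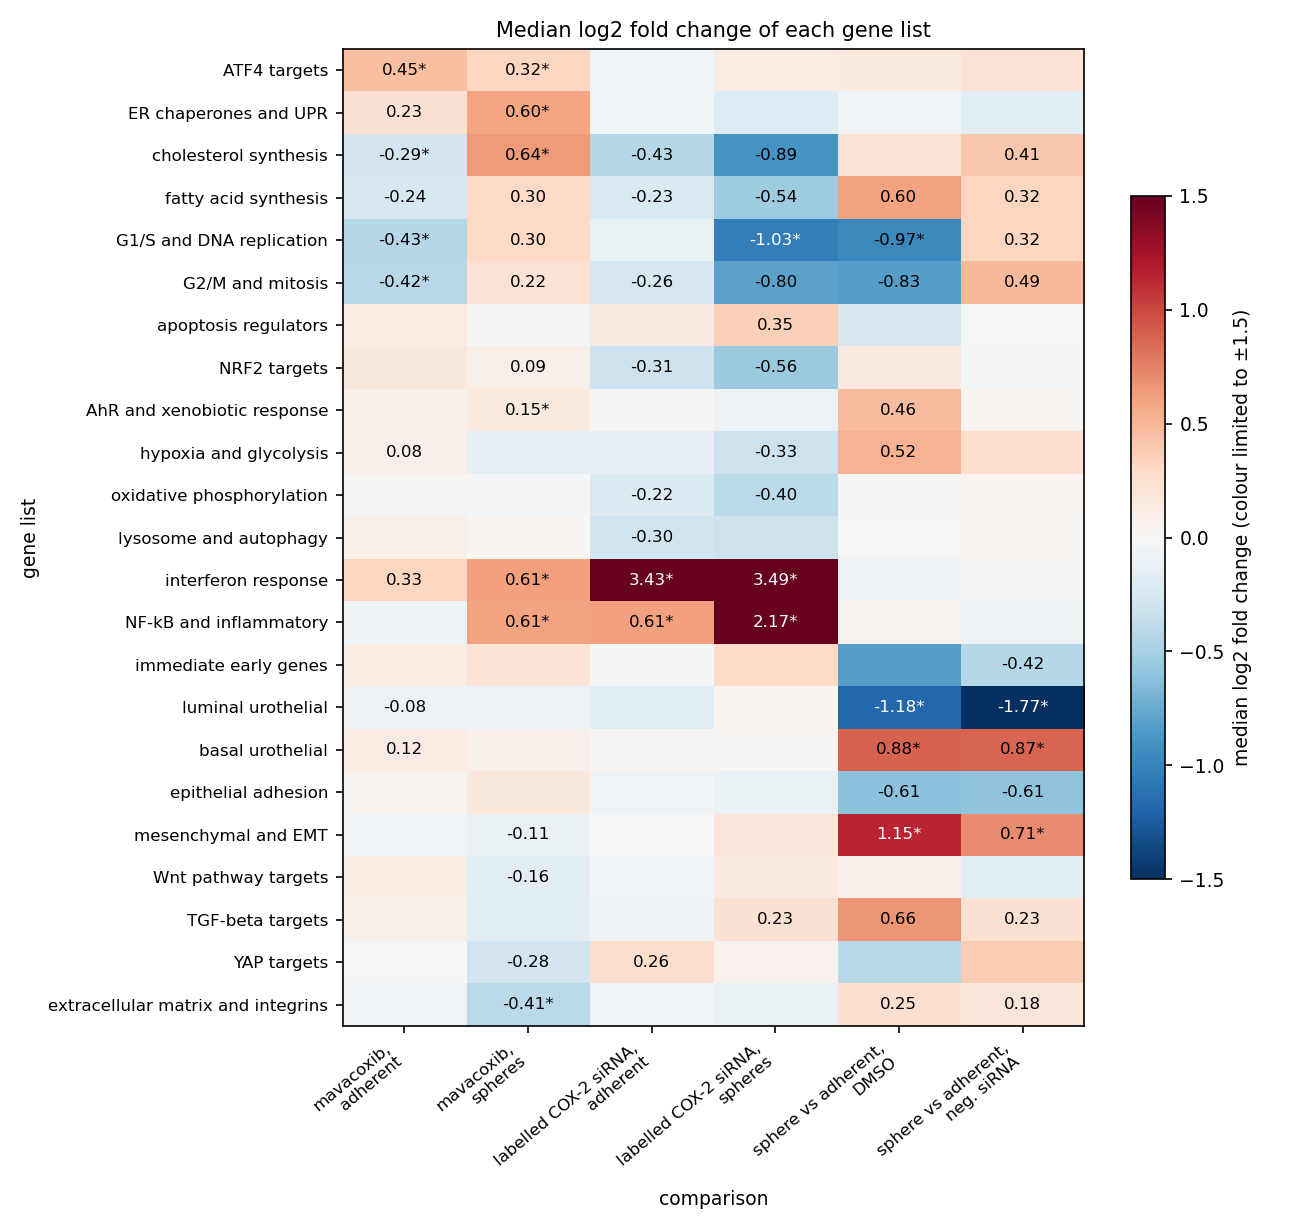
Median log2 fold change of each gene list (rows of the plot) in the 6 comparisons between groups (columns); the number is printed where the camera adjusted p was under 0.05, and an asterisk marks lists that also passed with an estimated correlation. Interferon genes stood at 3.43 and 3.49 in the arrays labelled COX-2 siRNA, replication genes at -0.43 and 0.30 with mavacoxib in adherent cells and spheres.

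In adherent cells, interferon-induced genes rose in the arrays labelled COX-2 siRNA, in which PTGS2 was not lower. DDX60, an interferon-induced RNA helicase, was higher by 6.53 ± 0.16, IFNL1 by 6.41 ± 0.22, the chemokine CCL5 by 6.19 ± 0.20 and USP18, which removes ISG15 from proteins, by 5.80 ± 0.20. With negative siRNA these genes averaged between 3.37 (USP18) and 4.45 (CCL5), under the median of all values of 4.82, so the differences are lower bounds where that signal is background. NFKBIA, the inhibitor of NF-kB that NF-kB itself induces, rose by 2.79 ± 0.13, and PMAIP1 by 2.15 ± 0.16. The largest fall was smaller, at -2.28 ± 0.40 for MORN2. All 32 interferon response genes rose (also adjusted over the list alone), with a median of 3.43 (camera adjusted p = 6.06e-89). NF-kB and inflammatory genes had 14 higher, 1 lower and 11 not passing of 26 (16 and 2 adjusted over the list alone, median 0.61, camera adjusted p = 1.06e-11). Both of these lists held with an estimated correlation.

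Cholesterol synthesis genes were lower in the adherent arrays labelled COX-2 siRNA, with 0 higher and 9 lower of 17 (the same adjusted over the list alone, camera adjusted p = 3.71e-06, adjusted p = 0.0648 with an estimated correlation); FDPS, the farnesyl diphosphate synthase, stood at -0.84 ± 0.12 and INSIG1 at -0.82 ± 0.13. NRF2 targets had 0 higher and 8 lower of 19 (0 and 9 adjusted over the list alone, camera adjusted p = 0.00073, adjusted p = 0.242 with an estimated correlation), such as PIR, an iron-binding nuclear protein, at -0.84 ± 0.10. The prostaglandin pathway had 0 higher and 3 lower of 20 (the same adjusted over the list alone, camera adjusted p = 0.573), namely the prostanoid exporter ABCC4 at -0.81 ± 0.15, the prostaglandin E synthase PTGES2 at -0.60 and the receptor gene PTGDR at -0.64. Mitosis genes had 1 higher and 10 lower of 34 (the same adjusted over the list alone, median -0.26). Their camera adjusted p was 0.000666, and 0.565 with an estimated correlation. The lower count was 6 with every array shifted to the same median. Replication genes had 1 higher and 9 lower of 33 (2 and 10 adjusted over the list alone) and did not pass (camera adjusted p = 0.0546). The arrays labelled COX-2 siRNA differed from the negative siRNA arrays at 2445 genes, 1046 higher and 1399 lower, 278 of them at least 2-fold. Without negative siRNA array 3 the count was 1566.

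Interferon and inflammatory genes rose in the sphere arrays labelled COX-2 siRNA, and genes of replication fell, while PTGS2 was higher. IFNL1 was higher by 7.53 ± 0.22, IFNB1, the interferon beta gene, by 6.95 ± 0.26, the guidance factor SEMA3A by 7.27 ± 0.15, CXCL10 by 7.09 ± 0.19 and the monocyte chemokine CCL2 by 6.15 ± 0.13. With negative siRNA these genes averaged between 2.11 (IFNB1) and 4.35 (CCL2), under the median of all values of 4.82, so their differences are lower bounds where that signal is background. TNF rose by 5.48 ± 0.21 and TNFAIP3, a feedback inhibitor of NF-kB, by 4.82 ± 0.16. E2F1 fell by 1.75 ± 0.11, the changes of CDC20, an activator of the anaphase-promoting complex, and CENPA, the centromeric histone, being -1.71 ± 0.10 and -1.65 ± 0.13. Interferon response genes had 31 higher, 0 lower and 1 not passing of 32 (the same adjusted over the list alone, median 3.49, camera adjusted p = 1.62e-44). NF-kB and inflammatory genes had 22 higher and 0 lower of 26 (the same adjusted over the list alone, median 2.17, camera adjusted p = 6.53e-24). Replication genes had 0 higher and 31 lower of 33 (the same adjusted over the list alone, median -1.03, camera adjusted p = 1.08e-16). These 3 lists held with an estimated correlation.

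Mitosis genes were lower in 32 of 34 cases and higher in 0 in the sphere arrays labelled COX-2 siRNA (the same adjusted over the list alone, median -0.80, camera adjusted p = 2.78e-13, adjusted p = 0.144 with an estimated correlation). Cholesterol synthesis had 0 higher and 11 lower of 17 (the same adjusted over the list alone, camera adjusted p = 3.42e-05, adjusted p = 0.0866 with an estimated correlation), and oxidative phosphorylation 0 higher and 12 lower of 23 (0 and 16 adjusted over the list alone, camera adjusted p = 0.000225, adjusted p = 0.0866 with an estimated correlation). In the prostaglandin pathway 5 genes rose and 3 fell of 20 (the same adjusted over the list alone, camera adjusted p = 0.452): beside PTGS2, the prostaglandin E2 receptor gene PTGER2 rose by 1.00 ± 0.25, and HPGD, which degrades prostaglandins, fell by 1.68 ± 0.23. Stem cell markers had 7 higher and 1 lower of 23 (the same adjusted over the list alone, camera adjusted p = 0.113), with SOX2 at 1.40 ± 0.22 and KLF4 at 1.65 ± 0.20. The count was 6356 genes, 2567 higher and 3789 lower, and 1387 changed at least 2-fold. With every array shifted to the same median the median of all genes was -0.15 in place of -0.04, and the share of higher genes 28.7% in place of 40.4%, so changes are relative to that shift.

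The difference between the labelled siRNA arms itself differed between spheres and adherent cells at 2489 genes, 1099 higher and 1390 lower in spheres. NF-kB and inflammatory genes had 19 higher and 1 lower of 26 (21 and 1 adjusted over the list alone, median 1.35, camera adjusted p = 5.21e-23), led by CCL2 at 6.21 ± 0.18. Replication genes had 0 higher and 27 lower of 33 (0 and 31 adjusted over the list alone, median -0.87, camera adjusted p = 1.52e-20). Both lists held with an estimated correlation, whereas mitosis genes, with 0 higher and 15 lower of 34 (0 and 22 adjusted over the list alone, camera adjusted p = 1.52e-11), had an adjusted p = 0.406 with an estimated correlation. PTGS2 differed by 0.83 ± 0.18 (adjusted p = 0.00354). Across genes the differences of both culture forms correlated at a Pearson r of 0.6 and a Spearman rho of 0.437. Among 1793 genes that passed in both, 96.1% moved the same way, 757 higher in both against 165 for independent lists and 966 lower in both against 325. Array weights gave 5445 genes; of 6 lists that passed, 3 did without COX-2 siRNA array 1 of the spheres, and the share of higher genes was 44.2% as deposited and 26.6% with every array shifted to the same median, which moved the median of all genes from -0.02 to -0.14.

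**Figure D3:**
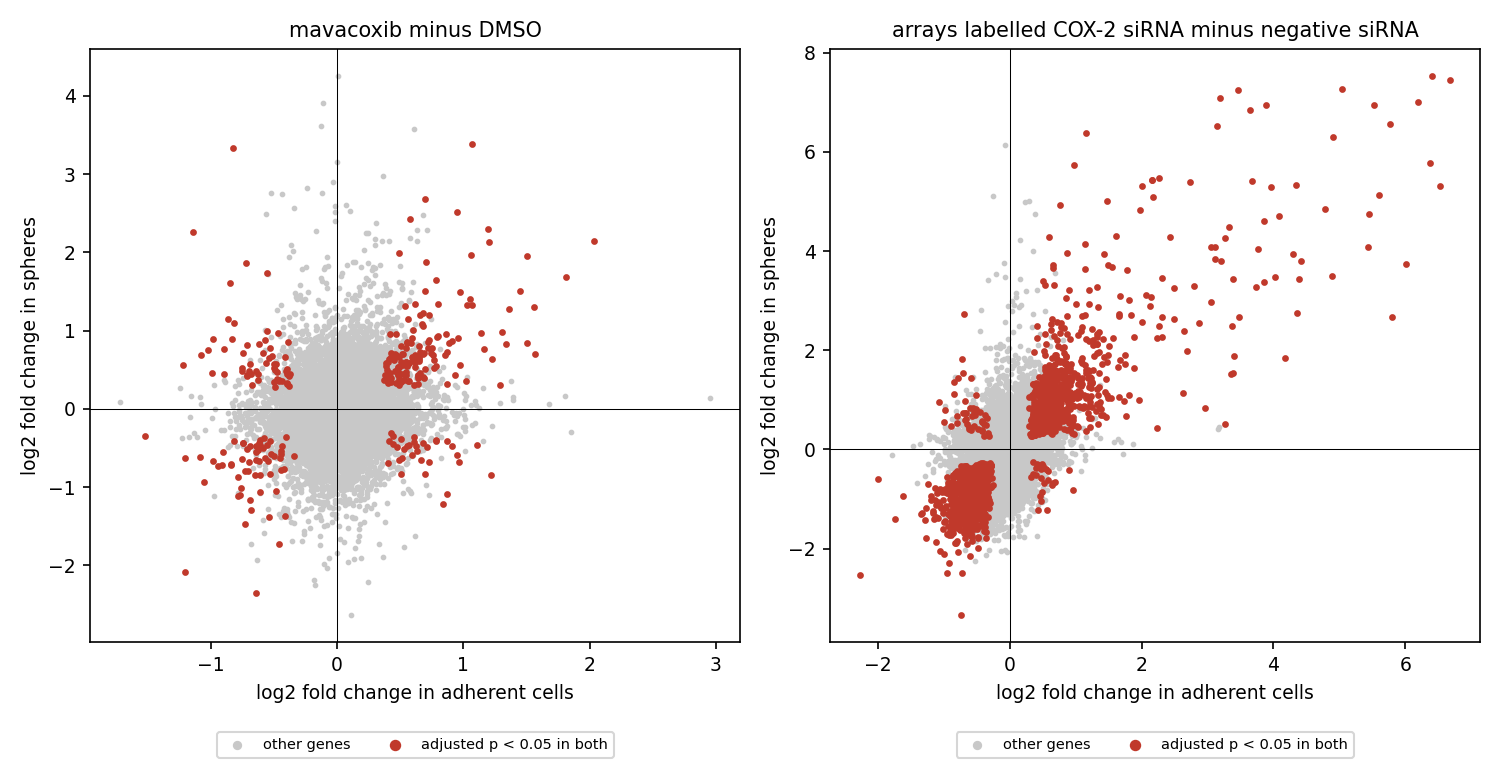
Log2 fold change in spheres (vertical axis) against that in adherent cells (horizontal axis) for 16295 genes, with mavacoxib on the left and between the arrays labelled COX-2 siRNA and negative siRNA on the right; red points passed in both culture forms. The Pearson r across genes was 0.172 on the left and 0.6 on the right.

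The change with mavacoxib was set against that in the arrays labelled COX-2 siRNA, in which PTGS2 was not lower. In adherent cells the mavacoxib change exceeded the siRNA change most for SPINK5, a protease inhibitor of epithelia, by 2.95 ± 0.22, and for the lipid transporter ABCA8, by 2.79 ± 0.23, and was below it for IFNL1, at -6.52 ± 0.30, and CCL5, at -5.83 ± 0.29. In spheres the mavacoxib change was above the siRNA change for the nuclear receptor NR4A1, by 4.17 ± 0.30, and for INSIG1, by 3.07 ± 0.18, and below it for SEMA3A, at -6.88 ± 0.22, and for GBP5, an interferon-induced GTPase, at -6.66 ± 0.23. PTGS2 differed by -0.45 ± 0.18 in adherent cells, which did not pass (adjusted p = 0.134), and by -1.21 ± 0.18 in spheres (adjusted p = 2.31e-05). The changes correlated across genes at a Pearson r of 0.090 in adherent cells (Spearman rho 0.050) and 0.143 in spheres (rho 0.034). In adherent cells 227 genes passed for both treatments, 78 higher in both against 27.3 for independent lists and 68 lower in both against 21.0, and 64.3% moved the same way. Another 59 were higher with mavacoxib and lower with the labelled siRNA against 36.6, and 22 the reverse against 15.7. In spheres 1965 genes passed for both and 54.9% moved the same way. Of these 543 were higher in both against 285, and 535 lower in both against 390. There 526 were higher with mavacoxib and lower with the labelled siRNA against 421, and 361 the reverse against 264. In both culture forms every combination of directions exceeded its number for independent lists. An excess of genes moving the same way does not by itself show a shared effect here. The test of the difference passed 1578 genes in adherent cells (3051 with array weights) and 5229 in spheres, 58.4% of them with a higher mavacoxib change; that share was 73.6% with every array shifted to the same median, which moved the median of all genes from 0.03 to 0.19. Mavacoxib and siRNA arrays also differed in time, 24 h against 48 h.

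These values rest on the direction of the labelled siRNA arms, and were computed again with the arms exchanged, an alternative chosen after seeing the data. With the siRNA change turned, SPINK5 stood at -1.05 ± 0.22, ABCA8 at 0.82 ± 0.23, IFNL1 at 6.30 ± 0.30 and CCL5 at 6.55 ± 0.29 in adherent cells. In spheres NR4A1 stood at 0.82 ± 0.30, SEMA3A at 7.67 ± 0.22 and GBP5 at 7.03 ± 0.23, while INSIG1, at 0.15 ± 0.18, did not pass (adjusted p = 0.574). PTGS2 stood at 0.22 ± 0.18 in adherent cells (adjusted p = 0.534) and 1.11 ± 0.18 in spheres (adjusted p = 5.85e-05). The highest values were then those of IFI44L, an interferon-induced gene, at 7.69 in adherent cells and IFNL1 at 11.44 in spheres. The difference passed for 1644 genes in adherent cells and 5253 in spheres, 58% and 42.3% of them higher, with 515 and 2706 shared with the test as labelled. The share moving the same way became 35.7% in adherent cells and 45.1% in spheres, and the Pearson r -0.09 and -0.143.

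Between control cultures with DMSO, spheres had lower luminal urothelial genes and higher basal and mesenchymal genes than adherent cells. The basal keratin KRT5 was higher in spheres by 8.42 ± 0.19, TP63, a transcription factor of basal epithelium, by 4.78 ± 0.18, and the epidermal keratins KRT1 and KRT10 by 7.90 ± 0.24 and 7.90 ± 0.29. The uroplakins UPK3A and UPK1A, membrane proteins of superficial urothelium, were at -7.50 ± 0.29 and -7.28 ± 0.18. CDH2, the N-cadherin gene, was higher by 5.08 ± 0.18 and TGFBI, a matrix protein induced by TGF-beta, by 5.92 ± 0.13, and the tight junction gene CLDN4 fell by 4.27 ± 0.20. The MHC class II genes DLA-DRA and DLA-DQA1 and their chaperone CD74 stood at -8.10 ± 0.21, -6.98 ± 0.17 and -7.34 ± 0.20. In the lower group these genes except CLDN4 (6.18) averaged between 2.57 (KRT1) and 4.54 (TP63), under the median of all values of 4.82. Without detection calls, their differences are lower bounds where that signal is background.

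Basal urothelial genes had 13 higher, 1 lower and 3 not passing of 17 (the same adjusted over the list alone, median 0.88, camera adjusted p = 4.42e-08), and luminal urothelial genes 3 higher, 15 lower and 4 not passing of 22 (3 and 16 adjusted over the list alone, median -1.18, camera adjusted p = 4.82e-06). Mesenchymal genes had 15 higher and 0 lower of 24 (the same adjusted over the list alone, median 1.15, camera adjusted p = 7.96e-08). Fibroblast markers passed in 3 of 12 cases, all higher (the same adjusted over the list alone, camera adjusted p = 0.532), with the collagen COL3A1 at 2.82 ± 0.23. Among all 16295 genes 3714 were higher, a share near that of the fibroblast markers. Leukocyte markers had 4 higher and 0 lower of 12 (the same adjusted over the list alone, camera adjusted p = 0.209), led by lysozyme, LYZ, at 3.79 ± 0.19, and endothelial and muscle markers 4 and 0 of 12 (the same adjusted over the list alone, camera adjusted p = 0.141), led by the VEGF receptor FLT1 at 3.85 ± 0.22. Replication genes had 2 higher and 27 lower of 33 (2 and 28 adjusted over the list alone, median -0.97, camera adjusted p = 1.1e-09), with CDC6 at -2.30 ± 0.13. These lists held with an estimated correlation except the fibroblast, leukocyte and endothelial ones, which passed neither test. Mitosis genes had 0 higher and 31 lower of 34 (1 and 32 adjusted over the list alone, camera adjusted p = 1.1e-09, adjusted p = 0.215 with an estimated correlation). Stem cell markers had 7 higher and 7 lower of 23 (the same adjusted over the list alone, camera adjusted p = 0.650), and so had no common direction. Among the lower ones, the retinaldehyde dehydrogenases ALDH1A1 and ALDH1A3 and PROM1, which encodes CD133, were at -7.93 ± 0.23, -5.48 ± 0.17 and -4.94 ± 0.15. Their sphere levels of 3.22, 3.83 and 3.28, and the adherent levels of COL3A1 (4.04) and FLT1 (3.44), were under 4.82 too, with the same limit.

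With DMSO, spheres differed from adherent cells at 7505 genes, 3714 higher and 3791 lower, 2903 of them at least 2-fold and 295 at least 16-fold. With every array shifted to the same median the median of all genes was -0.22 in place of -0.03, and 33.6% in place of 49.5% of the genes that passed were higher. PTGS2 was higher in spheres by 2.51 ± 0.13 (adjusted p = 1.56e-13), and the prostaglandin pathway had 8 higher and 4 lower of 20 (8 and 5 adjusted over the list alone, camera adjusted p = 0.192).

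**Figure D4:**
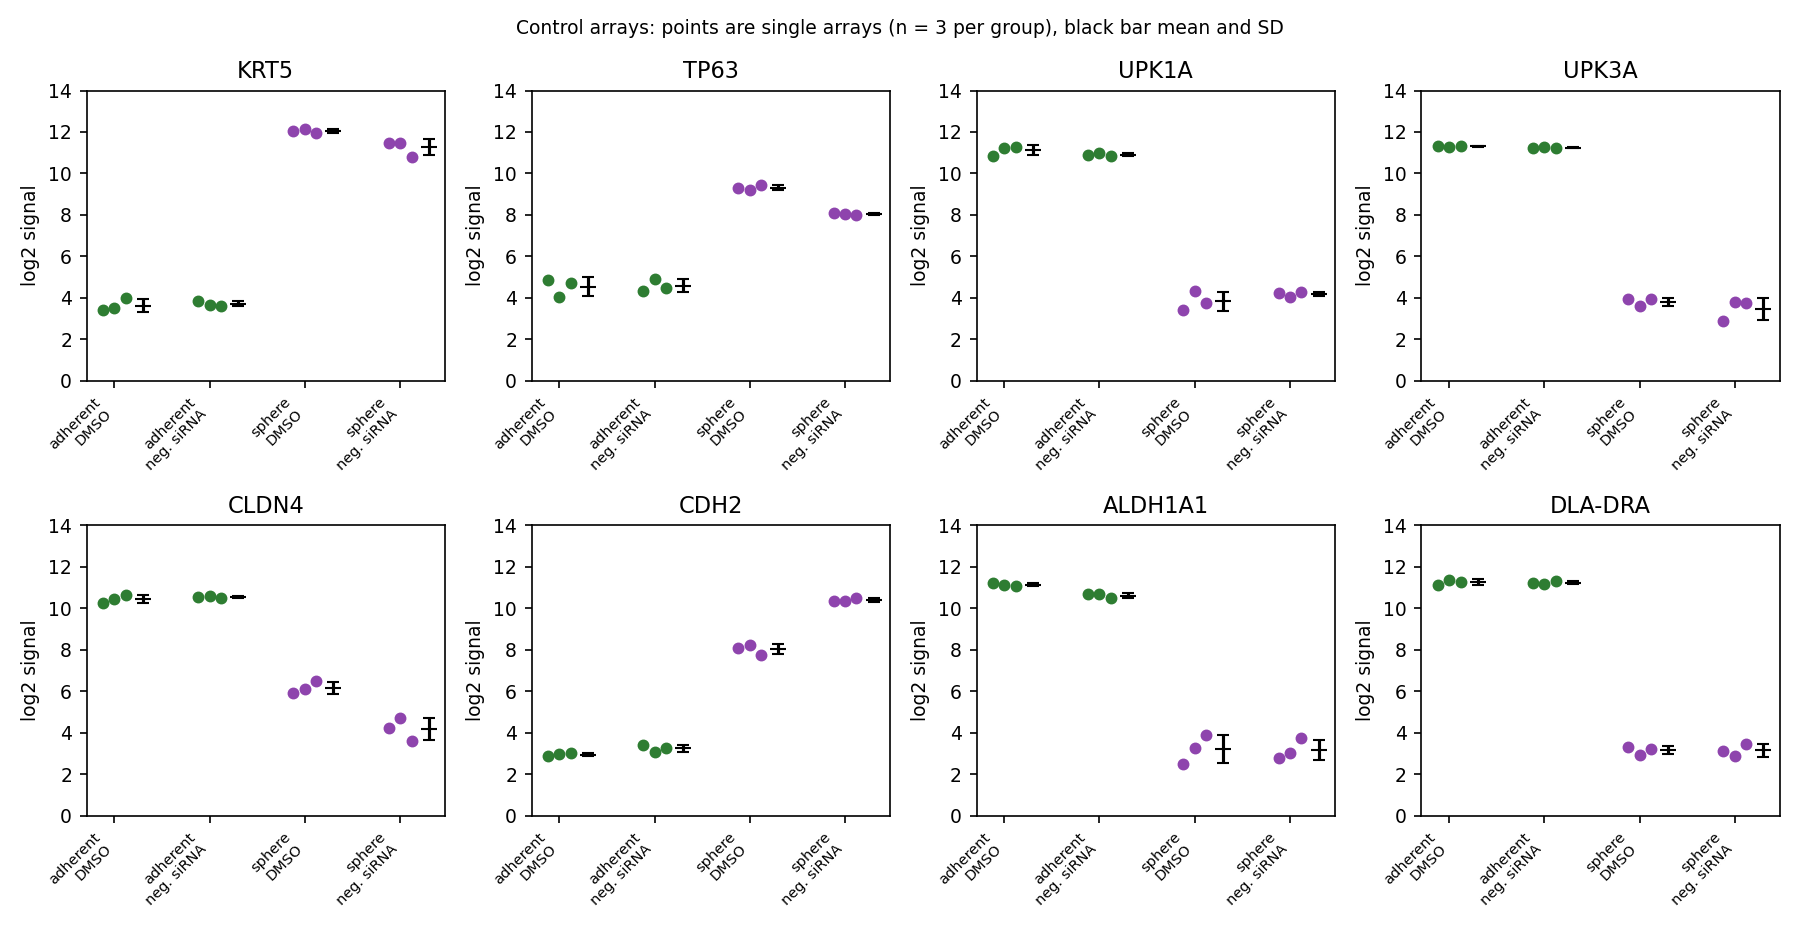
Log2 signal of 8 genes in the control arrays; points are single arrays, black bars the mean and SD (n = 3). KRT5 averaged 12 in spheres and 3.62 in adherent cells with DMSO, UPK3A 3.81 and 11.3, and the negative siRNA arrays lay on the same side for all 8 genes.

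With negative siRNA, luminal genes were again lower and basal and mesenchymal genes higher in spheres. KRT5 was higher in spheres by 7.54 ± 0.19, CDH2 by 7.15 ± 0.18 and PDPN, the podoplanin gene, by 7.84 ± 0.19, while UPK3A fell by 7.77 ± 0.29, DLA-DRA by 8.09 ± 0.21 and ALDH1A1 by 7.43 ± 0.23. In spheres the last 3 averaged 3.47, 3.16 and 3.18. In adherent cells KRT5 averaged 3.71, CDH2 3.25 and PDPN 3.36, and the same limit applies. Luminal genes had 3 higher and 18 lower of 22 (the same adjusted over the list alone, median -1.77, camera adjusted p = 5.02e-09), basal genes 13 higher and 1 lower of 17 (the same adjusted over the list alone, camera adjusted p = 3.33e-07) and mesenchymal genes 13 higher and 4 lower of 24 (14 and 4 adjusted over the list alone, camera adjusted p = 2.51e-05). These 3 lists held with an estimated correlation. Mitosis genes had 24 higher and 0 lower of 34 (25 and 0 adjusted over the list alone, camera adjusted p = 1.66e-06, adjusted p = 0.433 with an estimated correlation), and replication genes 16 higher and 4 lower of 33 (the same adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.436 with an estimated correlation), the latter call being lost when dim genes were left out. Replication counts were 8 higher and 4 lower with every array shifted to the same median, and 21 and 3 after quantile normalization. The mitotic kinesin KIF4A rose by 1.41 ± 0.12 and E2F1 by 1.11 ± 0.11.

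PTGS2 was lower in spheres with negative siRNA, by -0.68 ± 0.13 (adjusted p = 0.000155). Its difference between culture forms was -3.19 ± 0.18 relative to that with DMSO (adjusted p = 5.14e-11), tested after the values were seen. PTGES stood at -5.29 ± 0.19, with a sphere level of 3.82 and the same limit, and the prostaglandin pathway had 3 higher and 5 lower of 20 (the same adjusted over the list alone, camera adjusted p = 0.8). Fibroblast markers had 2 higher and 2 lower of 12 (2 and 1 adjusted over the list alone, camera adjusted p = 0.839), leukocyte markers 2 and 1 of 12 (2 and 0 adjusted over the list alone, camera adjusted p = 0.718), and endothelial and muscle markers 2 and 0 of 12 (the same adjusted over the list alone, camera adjusted p = 0.439). The count was 6955 genes, 3348 higher and 3607 lower, with 2469 at least 2-fold. Differences between culture forms correlated across genes between the DMSO and negative siRNA arrays at a Pearson r of 0.857 and a Spearman rho of 0.694, and 95.1% of 5236 genes that passed in both moved the same way, 2449 higher against 763 for independent lists and 2530 lower against 839. With every array shifted to the same median the median of all genes was -0.20 in place of -0.06 and the share of higher genes 34.1% in place of 48.1%.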

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

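The tests of exchanged siRNA labels, of a fault in 1 set of arrays and of low replication genes in the sphere DMSO arrays were chosen after the results were seen, as was the comparison of a transfection effect with the difference between the siRNA arms.

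Interferon genes were higher in the arrays labelled COX-2 siRNA than in those labelled negative siRNA, with medians of 3.43 in adherent cells and 3.49 in spheres. An effect of any transfection as the whole cause is argued against, since both arms were transfected and the negative siRNA arrays lay at list medians of -0.02 in adherent cells and 0.445 in spheres relative to DMSO (16 genes higher and 7 lower in spheres). Time differed there as well, and the experiment may have. The bound set beforehand, under 0.25 in both culture forms, was not met in spheres, so a smaller contribution stays open. PTGS2 was not lower in the arrays labelled COX-2 siRNA, at 0.333 in adherent cells (adjusted p = 0.0888) and 1.16 in spheres. Exchanged labels of the arms could not be told apart from correct labels with no net fall in PTGS2, whatever the reason. The adherent difference passed only with trend and robust variance (adjusted p = 0.0321, the range over all alternatives being 0.0321 to 0.302).

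Spheres and adherent cells differed at 7505 genes with DMSO and 6955 with negative siRNA. A fault of 1 set of arrays is argued against by the correlation of 0.857 across genes between these differences. Medians of 171 windows of 50 neighbouring genes spread 2.95 and 3.06 times as widely as after shuffling gene positions. They correlated at 0.948 between the controls. Different genomes in the culture forms, such as another line or a selected clone, would give such values, and the rule set beforehand for them was met. Ratios of 1.08 and 1.14 for mavacoxib in spheres and adherent cells and 1.16 for the siRNA arms of spheres lay within the shuffles, while 1.55 for the siRNA arms of adherent cells lay outside. A spread beyond the shuffles, though smaller than that between culture forms, thus also arose within the same culture form. The windows alone therefore cannot tell different genomes from a change of cell state. A change of cell state with the culture form, its medium included, stays open and was not tested.

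DNA replication genes fell with mavacoxib in adherent cells (median -0.43) and rose in spheres (0.30), a difference of 0.77, though the rise was lost at adjusted p = 0.169 with an estimated correlation. A single sphere array as the source of the camera call is argued against, since the lowest median without 1 of them was 0.217 and the highest camera adjusted p 0.000738. The sphere DMSO arrays lay at a median of -1.587 relative to the sphere negative siRNA arrays, and the sphere mavacoxib arrays at -1.25. Time and transfection differed as well, and in adherent cells the list median of negative siRNA minus DMSO was 0.367. These values alone therefore cannot tell low replication genes in the DMSO spheres from high replication genes with negative siRNA. Adherent cells with DMSO matched the DMSO spheres in time and lack of transfection. Relative to them the sphere DMSO arrays lay at a median of -0.967 (2 higher and 27 lower of 33). With negative siRNA, spheres lay at 0.323 relative to adherent cells (16 higher and 4 lower). Replication genes were thus low in the DMSO spheres relative to adherent cells with DMSO. Whether low levels with DMSO account for the rise was not decided. An effect of mavacoxib that depends on the culture form stays open.

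The effect of mavacoxib differed between culture forms at 1680 genes by the test of the difference. Beside IRF1 (4.24), CXCL10 (4.16) and IFNL1 (4.02), it was higher in spheres for DEFB1 (3.75) and IL29L (3.40), and lower for CHN1 (-2.82), PRR9 (-2.74), SLITRK6 (-2.45), S100A8 (-2.29) and FSTL1 (-2.26). List medians of the difference were 0.42 for endoplasmic reticulum chaperones, 0.88 for cholesterol synthesis, 0.64 for fatty acid synthesis, 0.77 for replication, 0.65 for mitosis, 0.043 for AhR response, 0.49 for interferon response and 0.56 for NF-kB genes. They were -0.24 for hypoxia, -0.26 for Wnt targets, -0.29 for YAP targets, -0.26 for extracellular matrix and -0.19 for nutrient transport. With an estimated correlation 7 of these 13 lists passed, and mitosis, interferon response, hypoxia, Wnt targets, YAP targets and nutrient transport did not.

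The difference between the labelled siRNA arms differed between culture forms at 2489 genes. It was higher in spheres for PTGS2 (0.83), CCL2 (6.21), C1S (5.37), CGA (5.22), TGM2 (4.77) and MMP3 (4.76), and lower for USP18 (-3.12), PLA2R1 (-2.75), LY6E (-2.75), MCOLN2 (-2.70) and LOC486151 (-2.59). List medians were 0.25 for ATF4 targets, -0.87 for replication, -0.59 for mitosis, 1.35 for NF-kB genes, 0.26 for immediate early genes and 0.24 for TGF-beta targets, of which 2 passed with an estimated correlation.

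Among 10888 features without exactly 1 gene name, signals not used in the comparisons passed the same test at 121 features for mavacoxib in adherent cells and 794 in spheres, 657 and 1983 between the siRNA arms in adherent cells and spheres, and 2185 and 2052 between culture forms with DMSO and negative siRNA.

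For the 6 comparisons of groups the 10 splits of 6 arrays are too few for a share under 0.05; 1 of 10, the real one, gave as many genes. The real counts and the highest of the other splits were 671 and 0, 3491 and 7, 2445 and 0, 6356 and 84, 7505 and 0, and 6955 and 1. Each other split mixed arrays of both groups, so a real difference widened the spread and few genes could pass. The low counts of the other splits are therefore no evidence against chance. Of 100 splits, 1 gave as many genes for the mavacoxib difference between culture forms (1680; highest other 1630), 2 for mavacoxib against siRNA in adherent cells (1578; 1644) and 2 in spheres (5229; 5253), where the highest others equal the counts with the siRNA arms exchanged. For the siRNA difference between culture forms 13 of 100 splits gave as many (2489; highest other 6282). Splits of a difference between effects can keep the treatment groups of 1 side whole and so hold real effects, and these 4 counts do not decide whether chance can be excluded.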

How the results depend on the processing

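All alternatives were planned except the exchange of the siRNA arms, which was chosen after seeing the data and by construction turned the correlations of mavacoxib with siRNA effects to -0.09 in adherent cells and -0.143 in spheres. Of 861 results for named genes, 761 kept their call in every alternative and 95 lost it in at least 1. The others lost no call but changed sign or gained a call in at least 1. The list tests were repeated with quantile normalization, without dim genes, with only the arrays of a comparison and with replicate blocks spanning both culture forms. They were also repeated with an estimated correlation, with fry and without each array. The other alternatives, array weights among them, were not applied to the list tests. In the repeated tests 32 of 85 list results kept their call, 33 lost it only with an estimated correlation and 20 otherwise. None changed the sign of its median under a scaling. Array weights gave 2472 genes for mavacoxib in adherent cells, 5535 in spheres, 3950 for their difference, 5445 for the siRNA difference between culture forms and 3051 for mavacoxib against siRNA in adherent cells. Mavacoxib in spheres gave 1904 genes with only its 6 arrays. In adherent cells it gave 425 with replicate blocks set within each culture form, apart for mavacoxib and siRNA arrays with their controls. With dim genes left out (10920 genes) 6 lists passed between culture forms with negative siRNA, and siRNA effects correlated at 0.667 between culture forms. Over all 16295 genes, Spearman's rho was 0.437 for siRNA effects between culture forms and 0.034 for mavacoxib with siRNA in spheres. With an estimated correlation 4, 7, 2, 3, 4, 3, 7 and 2 lists passed for mavacoxib in adherent cells and spheres, siRNA in adherent cells and spheres, culture forms with DMSO and negative siRNA, and the mavacoxib and siRNA differences. With fry, which does not compare a list with other genes, 17, 26, 32, 30 and 16 passed for siRNA in adherent cells and spheres, culture forms with DMSO and negative siRNA, and the siRNA difference. Leaving out an array gave 344 to 500 genes for mavacoxib in adherent cells, 1566 to 1985 for siRNA in adherent cells, and 3 to 8 lists for the siRNA difference. PTGS2, not called, ran from -0.227 to 0.048 for mavacoxib in adherent cells (0.048 without mavacoxib array 1), from -0.15 to 0.01 in spheres (0.01 without mavacoxib array 2) and from -0.10 to 0.17 for the difference, where it was -0.10 without adherent mavacoxib array 1 and -0.03 without sphere mavacoxib array 1. PTGS2 passed in 2 further settings, siRNA in adherent cells with trend and robust variance (adjusted p = 0.0321) and mavacoxib against siRNA in adherent cells with array weights (adjusted p = 0.0445). Leaving out arrays or genes leaves fewer of them to test; for the other changes the cause was not tested.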

Other observations

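The control arrays of each culture form also differed, which belongs to no planned comparison, since time and transfection changed together. The labels do not say whether these arrays came from the same experiment. In spheres, all 33 replication genes were higher with negative siRNA than with DMSO (33 higher and 0 lower; median 1.59), as were 33 of 34 mitosis genes (median 1.25). Hypoxia and glycolysis genes had 1 higher and 21 lower of 31 (median -0.47), and NF-kB and inflammatory genes 2 higher and 13 lower of 26. In all, 3091 genes were higher and 2667 lower.

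In adherent cells 1424 genes were higher and 833 lower with negative siRNA than with DMSO. Replication genes had 14 higher and 0 lower of 33 (median 0.37). PTGS2 was higher by 1.39 in adherent cells (adjusted p = 9.07e-07) and fell by 1.80 in spheres (adjusted p = 2.98e-10). The difference of these changes passed for 30 of 33 replication genes (median 1.30) and 32 of 34 mitosis genes (median 1.44), all higher in spheres.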
